A study of Homo sapiens with 6 samples.

How the data were processed

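The study measured chromatin occupancy by chromatin immunoprecipitation and sequencing (ChIP-seq) in A375, an established human melanoma cell line. An antibody against phosphorylated SMAD1/5/8, the transcription factors activated by bone morphogenetic protein (BMP) receptors, was used on cells with a stable knockdown of GDF6, a BMP family ligand, or with an EGFP control knockdown. There were 4 ChIP libraries, 2 per knockdown, and 2 inputs, 1 per knockdown. The inputs entered only as the background of the caller. The series design also names a reactivation of the downstream pathway, which was not analysed here. The numbers 1 and 2 in the titles were read as replicates, although for the GDF6 knockdown the titles alone could also mean 2 hairpins. The labels do not say whether libraries with the same knockdown came from separate cultures, so p-values over libraries measure only the spread between these libraries, which may be technical.

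Reads were aligned with Bowtie 1.0.0 to GRCh37, per the submitters' processing notes. Peaks were called per library, not on pooled replicates, with MACS2 2.1.1.20160226, per the file headers. The headers record duplicate-removed single-end alignments, 34-base tags, the input of the same knockdown as control, a q-value cutoff of 0.01, an effective genome of 2.7e+09 bases and local backgrounds over 1000 and 10000 bp. Each deposited peak has a pileup signal, which is the number of extended reads that cover the summit. It has a fold ratio of that pileup over the local input background, each with 1 added, as deposited. It also has a deposited −log10 p-value and −log10 q-value, and a width (a further deposited quantity, in bp). These values are the authors' own for each peak. The larger library of a ChIP and input pair was scaled to the smaller, per the file headers, so the shGDF6 pileups had been multiplied by 0.986 and 0.979 while the shGFP pileups were unscaled. Dividing by these factors returned whole reads, within 0.02, for 100% of the peaks. The reads at the summit were then scaled to reads per 1e6 tags of the library (RPM). The local background was taken back from the pileup and its fold ratio. A Poisson p rebuilt from both differed from the deposited −log10 value by a median of at most 0.000965 in any library.

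The ChIP libraries held 33038786 and 33390779 tags after filtering (shGFP 1 and 2) and 35454487 and 35700677 (shGDF6 1 and 2). The fragment lengths that the caller used were 480, 459, 445 and 450 bp, and the narrowest peak of each list had that width. A summit of 23 reads was the lowest one called.

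Peaks of different lists that overlapped by at least 1 bp were joined into 1 region. Where a list had several peaks in a region, the one with the highest fold stood for it. Peak counts per library were compared on the log2 scale by a two-sided exact permutation test over the 6 splits of the 4 libraries, whose smallest possible p is 0.333. Overlap of 2 lists was compared with 10000 circular shifts of the shorter list along the GRCh37 chromosomes, one-sided, with Benjamini-Hochberg adjustment over 6 pairs. Chromosome lengths came from GenomeInfoDb 1.38.1. Values of 2 sets of peaks within a list were compared by two-sided permutation tests with 100000 resamples, or exactly where a set held fewer than 10 peaks. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. The shift test was checked on 40 pairs of simulated lists of the size of the 2 shGFP lists. It called 0 of 40 unrelated pairs, and 40 of 40 pairs with 30 planted shared peaks. The simulated peaks were placed at random without the clustering of the real lists. The check therefore covers the working of the test and not its error rate on these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 were used.

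The rule for the regions named in the text was fixed before the data were examined. It took the 15 regions with the highest lower-of-2 fold among those in both shGFP lists and neither shGDF6 list. It also took up to 10 regions in both shGDF6 lists and neither shGFP list, 10 regions in all 4 lists, and the top 5 of each list. The regions at chromosome 12, 133779280 to 133781075, and chromosome 20, 30182432 to 30184450, fall outside this rule and were chosen after their values were seen. The same plan named gene lists (BMP targets and pathway members, activin targets, neural crest, melanocyte, apoptosis and MAPK genes, with highly transcribed and liver genes as controls). The reference tables at hand were of GRCh38, so a GRCh37 annotation and genome were not used here. The 3 planned results that need them, the position of peaks relative to genes, gene lists near peaks and SMAD motifs under summits, were therefore not run, regions are given by coordinate, and occupancy at GDF6 itself was not analysed here. All coordinates are GRCh37 and 1-based.

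The alternatives tried were stricter q and fold cutoffs, other overlap rules, lists of equal length, merged neighbours, a pairing by replicate number and leaving out each library. The comparison of summit reads, the comparison of control regions with and without a knockdown call, and the tests of peaks per chromosome were added after the data had been seen. So were these alternatives: a common p cutoff, a common smallest width, the shGFP input as background for shGDF6 summits, scaling by fragment length, only regions with aligned summits, a crossed pairing and the removal of 1 cluster.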

Results

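Phospho-SMAD1/5/8 occupancy was profiled by ChIP-seq in A375 melanoma cells that carried a stable knockdown of GDF6 (shGDF6, 2 libraries) or an EGFP control knockdown (shGFP, 2 libraries). The comparison asks how SMAD1/5/8 occupancy differs when the BMP ligand GDF6 is depleted. Sequencing depth was alike in the 4 libraries, at 33038786 and 33390779 tags in shGFP 1 and 2 and 35454487 and 35700677 in shGDF6 1 and 2. Summit reads are given per 1e6 tags of the library (RPM). The values are the authors' peak calls, made in each library against the input of the same knockdown. Peaks were narrow, with a median width of 716, 620.5, 710.5 and 604 bp in shGFP 1, shGFP 2, shGDF6 1 and shGDF6 2. Fold enrichment over the input was modest, with medians of 3.71, 3.84, 4.38 and 4.22 in the same order.

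Fewer occupied sites were called in both GDF6 knockdown libraries than in either control library. The control lists held 1703 (shGFP 1) and 260 peaks (shGFP 2), and the knockdown lists 62 (shGDF6 1) and 45 (shGDF6 2). The geometric means were 665 and 52.8, a 12.6-fold lower count after knockdown (log2 difference -3.66). The called sequence summed to 1315 and 178 kb in the controls and to 47.0 and 32.5 kb in the knockdown libraries. The 2 controls differed by 6.55-fold from each other, more than the 4.19-fold and 5.78-fold between shGFP 2 and the 2 knockdown lists. The knockdown libraries differed by 1.38-fold. The SD of the log2 count was 1.92 for shGFP and 0.33 for shGDF6 (n = 2 each), and the two-sided exact permutation test gave p = 0.333, the smallest value that 2 against 2 libraries allow. Without shGFP 1 the count was 4.92-fold lower after knockdown, without shGFP 2 it was 32.2-fold lower, and with only peaks of at least 5-fold enrichment it was 6.42-fold lower. In most regions called in both groups the local input background was higher in the shGFP comparison. The fold cutoff may therefore not be equally strict in both groups.

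**Figure D1:**
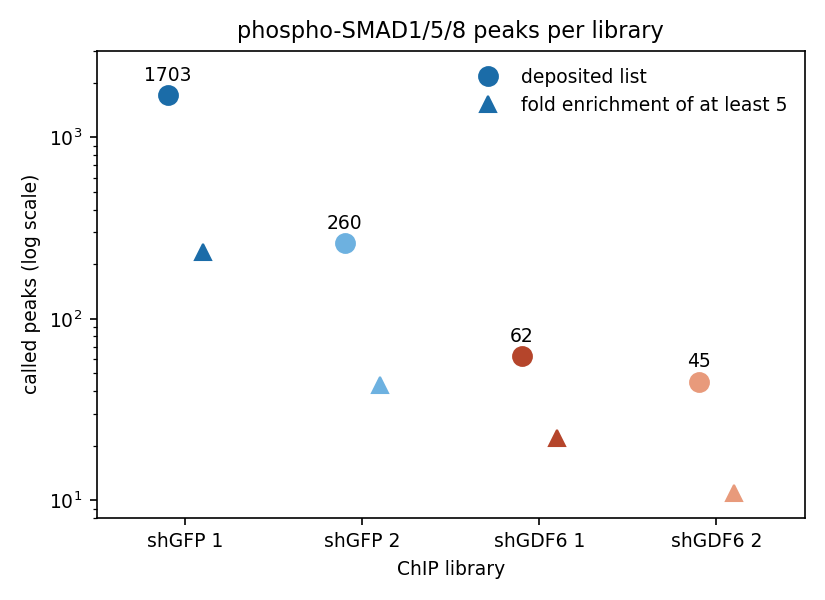
Number of phospho-SMAD1/5/8 peaks in each ChIP library on a log axis, for the deposited list (circles, with the count) and for peaks with a fold enrichment of at least 5 (triangles). Both knockdown libraries (62 and 45 peaks) lie under both controls (1703 and 260), and the controls are 6.55-fold apart.

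The occupied sites of the shorter lists were largely a subset of the sites of shGFP 1. Of the 260 peaks of shGFP 2, 253 (97.3%, 95% interval 94.5 to 98.9) overlapped a peak of shGFP 1. The same held for 49 of the 62 peaks of shGDF6 1 (79.0%, 66.8 to 88.3) and 37 of the 45 of shGDF6 2 (82.2%, 67.9 to 92.0). Between the knockdown replicates, 32 of the 45 peaks of shGDF6 2 overlapped shGDF6 1 (71.1%, 55.7 to 83.6). Circular shifts of the lists gave a mean of at most 0.251 overlapping peaks for any of the 6 pairs of lists, and each pair passed the shift test (permutation p = 0.0001, the smallest that 10000 shifts can give, 0.0001 after adjustment over 6 pairs). This test compares positions in these lists and not the conditions. With a reciprocal overlap of at least 50%, 26 peaks of shGDF6 1 and 17 of shGDF6 2 matched shGFP 1.

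Joining the 4 lists gave 1724 regions, of which 250 were called in both control libraries. Of these, 205 (82.0%, 95% interval 76.7 to 86.6) were called in neither shGDF6 list, 22 (8.80%, 5.60 to 13.0) in 1 and 23 (9.20%, 5.92 to 13.5) in both. In the opposite direction, 6 of the 31 regions called in both shGDF6 lists (19.4%, 7.45 to 37.5) were called in neither shGFP list. The share of 82.0% follows in large part from list length, since the knockdown lists made up 73 regions and at least 177 of the 250 (70.8%) had to be without a knockdown call. A region that misses the q cutoff in a list is not shown to be free of SMAD1/5/8 there. Of the 230 control regions whose −log10 p in both controls reached 9.23, the smallest value called in shGDF6 1, 191 (83.0%, 77.6 to 87.7) were called in neither knockdown list. With each list limited to its 45 most significant peaks, 16 of 33 control regions (48.5%) were in neither knockdown list. When the shGDF6 summits were set against the shGFP input, 27 of the 45 control regions with a knockdown call still passed. Only called summits could be retested, so this number could fall but not rise. Without shGFP 2, 1644 of the 1703 peaks of shGFP 1 (96.5%) were in neither knockdown list. That share follows almost wholly from list length, since the knockdown lists made up only 73 regions.

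**Figure D2:**
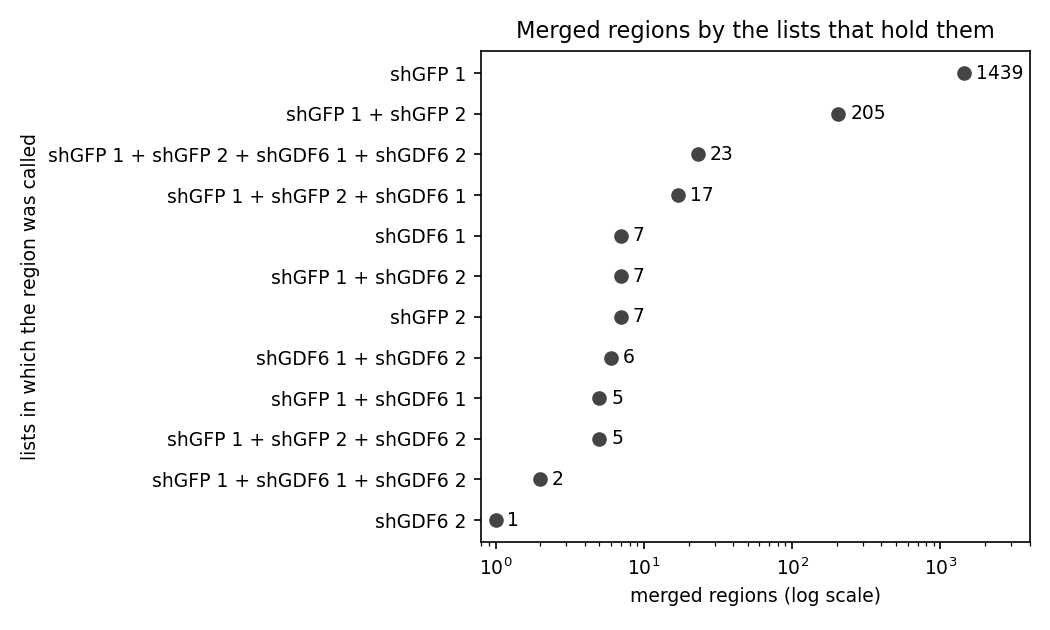
Number of merged regions on a log axis for each combination of lists in which a region was called. Of the 250 regions in both shGFP lists, 205 are in no shGDF6 list and 23 are in all 4 lists. Of the 31 regions in both shGDF6 lists, 6 are in no shGFP list.

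Ranked by the lower of the 2 control folds, the control sites with no knockdown call were led by regions on chromosomes 7, 6, 14 and 3. The region at chromosome 7, 147207058 to 147209160, had a fold enrichment of 13.6 in shGFP 1 and 8.08 in shGFP 2. Its summit held 2.82 ± 1.11 RPM (SD, n = 2). It counted as called in 1 list with a reciprocal overlap of at least 50%, and in 2 with summits within 200 bp. The region at chromosome 6, 16158927 to 16160103, followed with 13.8-fold and 7.79-fold enrichment and 2.19 ± 0.93 RPM (SD, n = 2). Enrichment was 7.71-fold and 7.04-fold at chromosome 14, 100942481 to 100943473, with 1.48 ± 0.14 RPM. It was 10.5-fold and 6.74-fold at chromosome 3, 105073405 to 105074992, with 2.73 ± 1.15 RPM (SD, n = 2 each). At the chromosome 6 and 14 regions the local background equalled the genome-wide background of the library (5.87 and 5.68 reads in shGFP 1 and 2). The chromosome 14 summit lay below the median of 1.61 RPM of the 205 control regions with no knockdown call, so its rank rests on a low background. Over the first 15 regions by this rank the lower of the control values ran from 5.65-fold to 8.08-fold. The largest fold of shGFP 1 was at chromosome 22, 41116692 to 41118047, with 14.6-fold in shGFP 1, 9.65-fold in shGFP 2 and 6.56-fold in shGDF6 1, and no call in shGDF6 2.

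The 23 regions called in all 4 lists included the 5 regions of highest fold enrichment in each knockdown list. The highest fold in shGDF6 1, 9.53, was at chromosome 6, 19803571 to 19806239, and the highest in shGDF6 2, 8.16, at chromosome 1, 23884477 to 23889605. The chromosome 6 summit held 239 and 148 reads in shGFP 1 and 2 and 144 and 114 in shGDF6 1 and 2, or 5.83 ± 1.98 against 3.63 ± 0.61 RPM (SD, n = 2 each). On chromosome 2, the region at 8817398 to 8820912 had 4.32 ± 0.12 against 2.66 ± 0.11 RPM, that at 85998588 to 86000189 had 4.01 ± 1.01 against 2.90 ± 0.17, and that at 79620004 to 79621846 had 3.56 ± 1.01 against 2.05 ± 0.41 (SD, n = 2 each). A further region on chromosome 2, 110863353 to 110864540, had 2.77 ± 1.04 against 1.08 ± 0.03, a ratio of the means of 2.56 that was the largest of the 23. At chromosome 22, 23863157 to 23864760, the values were 3.36 ± 0.34 and 2.61 ± 0.09. The smallest ratio, 0.90, was at chromosome 12, 133779280 to 133781075, with 0.86 ± 0.20 in shGFP and 0.96 ± 0.08 in shGDF6. The summits there lie at different positions (133779677 and 133779890 in shGFP 1 and 2, 133780442 and 133780720 in shGDF6 1 and 2).

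Summit reads in these 23 regions were lower after knockdown by a median of 1.52-fold (log2 -0.61, range -1.31 to 0.17). These regions had to be called in both knockdown libraries, which favours sites where the knockdown reads were high. The value of 1.52-fold thus does not describe the control regions without a knockdown call. In 20 of the 23 regions both knockdown values lay below both control values, where chance gives 16.7% of regions, and in 0 regions above both. Without shGFP 1 the median log2 difference was -0.30. The regions are not independent, because a difference between whole libraries moves all of them, and 2 against 2 libraries cannot pass an exact permutation test at a single region. The controls again differed from each other, by a median of 1.47-fold in the same 23 regions, while shGFP 2 was 1.18-fold and 1.25-fold above shGDF6 1 and shGDF6 2, and shGDF6 1 was 1.09-fold above shGDF6 2. The local input background also differed. It was higher in the shGFP comparison in 20 of the 23 regions, by a median of 1.40-fold, so fold enrichments of the groups are over unequal backgrounds. By the deposited fold over input the order was mixed, and in most of the 23 regions neither group lay wholly above the other. At chromosome 22, 23863157 to 23864760, both knockdown folds lay above both controls (7.89 and 7.51 against 6.33 and 5.25). At chromosome 2, 110863353 to 110864540, both lay below (5.64 and 5.46 against 10.8 and 6.82). The lower summit reads thus hold before correction for input.

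**Figure D3:**
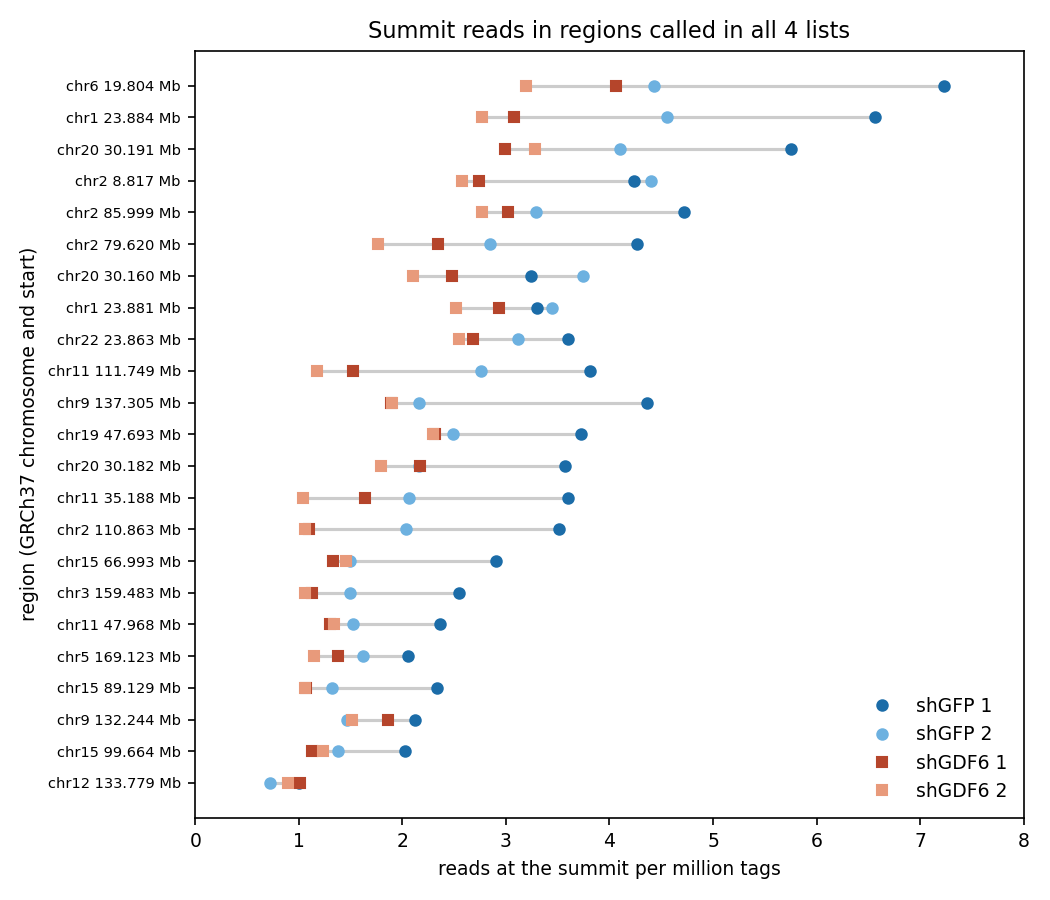
Reads at the summit per 1e6 tags (RPM) in each of the 23 regions called in all 4 lists, 1 row per region (GRCh37 chromosome and start), with circles for shGFP and squares for shGDF6 and a grey line over the range. In 20 of the 23 rows both squares lie to the left of both circles, and shGFP 2 lies mostly between shGFP 1 and the knockdown libraries.

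Neighbouring regions called in all 4 lists lay at 2 loci. On chromosome 20, 6 control regions lay within 39.1 kb (30158243 to 30197382), of which 3 were called in all 4 lists and 1 in 1 knockdown list. The strongest, at 30191303 to 30193783, had 4.93 ± 1.17 RPM in shGFP and 3.13 ± 0.20 in shGDF6. That at 30160224 to 30161750 had 3.49 ± 0.36 against 2.29 ± 0.27, and that at 30182432 to 30184450 had 2.86 ± 1.00 against 1.98 ± 0.27 (SD, n = 2 each). On chromosome 1, 2 regions within 8.98 kb were called in all 4 lists. The one at 23880624 to 23882570 had 3.37 ± 0.10 against 2.73 ± 0.29 RPM. The neighbouring region at 23884477 to 23889605 had 5.56 ± 1.43 against 2.92 ± 0.21 (SD, n = 2 each), and is a single wide peak in shGFP 1 but 3, 3 and 2 peaks in shGFP 2, shGDF6 1 and shGDF6 2.

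**Figure D4:**
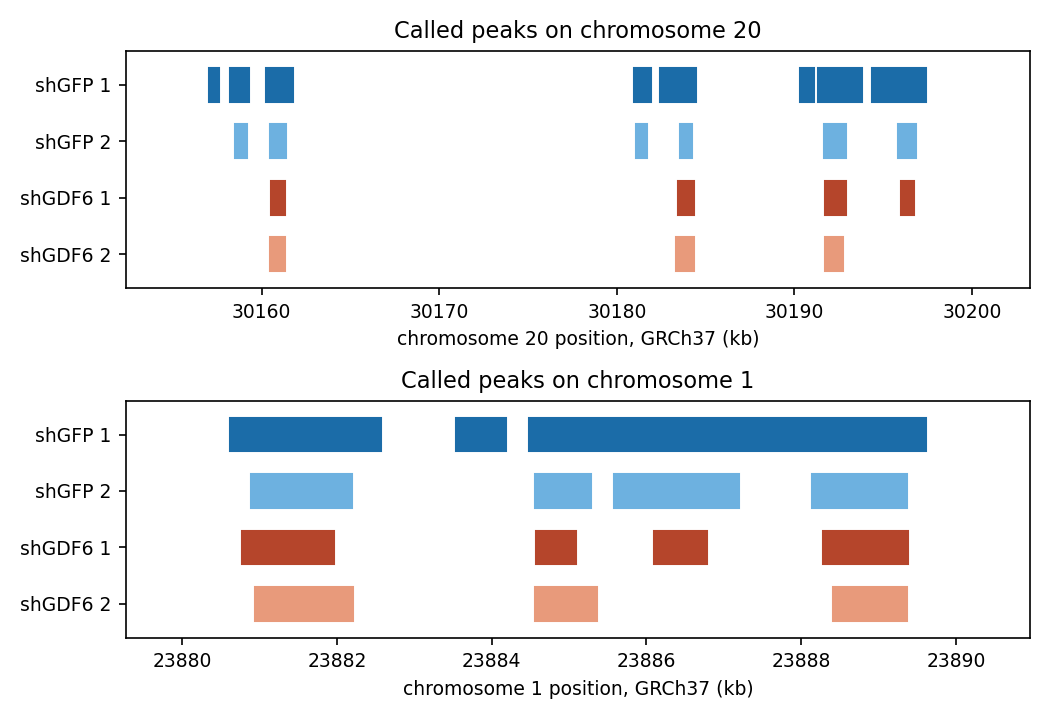
Called peaks of each library as boxes along GRCh37 positions in kb, on chromosome 20 (6 control regions, 3 of them in all 4 lists) and chromosome 1 (2 control regions, both in all 4 lists). Boxes show positions only, and on chromosome 1 a single wide box of shGFP 1 (23884477 to 23889605) spans 3, 3 and 2 boxes of shGFP 2, shGDF6 1 and shGDF6 2.

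The 6 regions called in both knockdown lists and in neither control list lay on chromosomes 1, 3, 4, 19, 22 and X. The region at chromosome 4, 177805157 to 177805751, had 5.05-fold and 4.83-fold enrichment in shGDF6 1 and 2. At chromosome 19, 44980501 to 44981942, the values were 4.25-fold and 4.32-fold, and at chromosome 1, 227842334 to 227843439, 3.92-fold and 4.04-fold. The summits of this chromosome 1 region lie at 227842599 in shGDF6 1 and 227843027 in shGDF6 2. It counted as called in 1 list with summits within 200 bp or a reciprocal overlap of at least 50%. The regions at chromosome 22, 38369376 to 38370284, chromosome X, 77359185 to 77360100, and chromosome 3, 75786186 to 75786992, had lower values of 3.57-fold, 2.86-fold and 2.34-fold in the weaker of the lists. The control libraries have no value at these positions, so the difference there was not tested.

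Control sites with a knockdown call had more summit reads in the controls. A call is itself a cutoff on summit reads over background. Sites with more reads in 1 library would thus tend to pass more often in another, with or without an effect of the knockdown. The tests below take regions or peaks as units, and neighbouring ones are not independent. They describe the lists and not the conditions. The 45 control regions called in at least 1 shGDF6 list had a median of 2.64 RPM at the shGFP summit, against 1.61 for the 205 others. Geometric means differed by 1.53-fold (permutation test, p = 1e-05, the smallest that 100000 resamples can give, 1e-05 after adjustment over 2 tests). Of the 63 control regions with the most reads, 29 (46.0%, 33.4 to 59.1) had a knockdown call, against 2 of the 62 with the fewest (3.23%, 0.393 to 11.2). By fold enrichment the order was not steady. In 4 sets of 65 peaks of shGFP 2, from highest to lowest fold, 35.4%, 7.69%, 12.3% and 16.9% overlapped a knockdown peak. The 45 regions also had a higher local background in the shGFP input than the 205 others, by 1.31-fold (permutation p = 1e-05, adjusted 1e-05). Within shGFP 1, the 250 peaks shared with shGFP 2 had a median fold enrichment of 5.32 against 3.56 for the 1453 others (log2 difference of means 0.58, permutation p = 1e-05, adjusted 2.5e-05 over 5 such tests). The 59 peaks of shGFP 1 shared with a knockdown list had 5.57 against 3.68 (0.58, permutation p = 1e-05, adjusted 2.5e-05). Within shGFP 2, the 47 peaks shared with a knockdown list had 4.42 against 3.76 (0.19, permutation p = 0.0019, adjusted 0.0032). Within the knockdown lists, peaks shared with a control and peaks not shared did not pass the test (4.48 against 4.03 in shGDF6 1, permutation p = 0.094, adjusted 0.12; 4.33 against 4.10 in shGDF6 2, exact permutation p = 0.19, adjusted 0.19).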

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

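The tests with a common p cutoff, the shGFP input for the knockdown summits, fragment length, aligned summits and a crossed pairing were chosen after the data had been seen, as was the comparison of summit reads. The direction of the peak count held under each alternative run, with log2 differences between -3.89 and -2.68 apart from leaving out a control library, and leaving out 1 library at a time gave -5.01 (without shGFP 2) to -2.30 (without shGFP 1). Restricting to chromosomes 1 to 22 and X removed no peak, so that setting tests nothing. One p cutoff for all lists left 1443, 241, 62 and 43 peaks, and 4.67-fold between the groups without shGFP 1. With the replicate block (libraries with the same number paired) the log2 difference was -3.66 and the exact sign-flip p was 0.5, the smallest that 2 pairs allow. The deviations of same-numbered libraries correlated at -0.129 over 23 regions and the labels do not say that a number marks a shared day. A crossed pairing sets 1703 against 45 and 260 against 62 calls. With a reciprocal overlap of at least 50%, 26 peaks of shGDF6 1 and 17 of shGDF6 2 matched shGFP 1, against 49 and 37 with 1 bp, and the cause was not tested. With each list limited to 45 peaks the overlaps were 34 for the shGFP lists, 20 and 16 for shGDF6 1 and 2 with shGFP 1, and 19 and 14 with shGFP 2, where the shorter lists hold fewer peaks by construction, while that of shGDF6 2 with shGDF6 1 was 28 against 32 in the full lists. The share of control regions in no knockdown list was then 48.5%, and 89.2% with the shGFP input as background for the knockdown summits, a setting that could only raise it. Leaving out 1 library at a time gave 81.9% (without shGFP 1) to 96.5% (without shGFP 2), and 89.2% without shGDF6 1. The 96.5% follows almost wholly from list length, since the knockdown lists made up 73 regions against the 1703 peaks of shGFP 1. The other rules for overlap and cutoff left the share of control regions in no knockdown list between 82.2% and 85.4%. Scaling by fragment length left the median summit difference at 1.45-fold, and the 20 regions with aligned summits gave 1.54-fold. Leaving out 1 library at a time moved its log2 value of -0.61 to between -0.86 (without shGFP 2) and -0.30 (without shGFP 1). Of the 31 regions named for being shared or missing, the number of calling lists was kept for 22 with lists of 45 peaks and for 27 or more under each other rule. Other promoter widths, gene distances and motif windows were not run, since no annotation or genome of the build was used here. No setting varied the depth, and the lowest called summits held 23, 24, 26 and 30 reads in shGFP 1, shGFP 2, shGDF6 1 and shGDF6 2.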

Other observations

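The tests of peaks per chromosome, of tags, of neighbouring regions, of aligned summits, of the least spread between groups and without 1 cluster were chosen after the values they concern had been seen. Those of a common cutoff, of a common factor, of a factor in shGFP 2 and of split signals were added after the peak lists had been read but before their own results were seen. The exact test of peak counts was fixed before the data were examined, and was set against the knockdown as an explanation after its value was seen. Peaks were unevenly spread over the chromosomes. In shGFP 1, chromosome 20 held 76 peaks where its length gives 35.3 (1.21 per Mb), chromosome 17 held 81 against 45.5, chromosome 12 held 113 against 75.1 and chromosome 1 held 188 against 139.8. These passed a two-sided binomial test adjusted over the chromosomes (adjusted p = 1.6e-08, 9.2e-06, 0.00015 and 0.00022). Fewer peaks than by length were on chromosomes X (33 against 87.1), 14 (34 against 60.2), 18 (26 against 43.8), 4 (83 against 107.2) and 16 (34 against 50.7), with adjusted p of 6.2e-10, 0.0011, 0.015, 0.038 and 0.038. Peaks are the units of this test and neighbouring peaks are not independent. In shGDF6 1 and 2, chromosome 20 held 6 of 62 and 6 of 45 peaks. The expected counts use full chromosome lengths, including gaps and sequence to which reads cannot be mapped. Gene content, copy number and such sequence were not separated here.

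The first pattern is the lower number of called regions in both knockdown libraries. Fewer tags are excluded, because the shGDF6 libraries had 1.07 times the tags of the controls. A stricter summit cutoff in the shorter lists does not account for the difference, because 1 common p cutoff left an 11.4-fold difference, and 4.67-fold without shGFP 1. With a common smallest width as well it was 12.7-fold. The deposited peaks were only filtered and not called again, so a stricter cutoff along the width of a peak was not excluded. One factor of weaker enrichment at all sites stays open, although the bound set beforehand to exclude it was met. The measure was the log2 ratio of summit excess, the summit reads above the genome background. Its variance was 2.23 times as large between as within the groups (95% bootstrap interval 1.09 to 4.67, 23 regions). In the 20 regions with aligned summits it was 1.90 (0.989 to 3.73). For the excess over the local background the values were 2.09 (1.14 to 4.15) and 1.93 (1.03 to 3.80). That bound was too weak, because replicates may be technical and variation between cultures would then raise the ratio, and the SDs for shGFP 2 against shGDF6 1 and 2 (0.362 and 0.412) were near that within shGFP (0.337, against 0.221 within shGDF6 and 0.449 and 0.471 for shGFP 1 against shGDF6 1 and 2), with a least-between to larger-within variance ratio of 1.15 (0.362 to 3.10). A lower occupancy caused by GDF6 depletion also stays open, since the exact permutation p of 0.333 cannot be smaller with 2 against 2 libraries.

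The second pattern is the 6.55-fold difference between the control replicates, for which no biological explanation was tested. The tags do not account for it, since shGFP 2 had 1.01 times those of shGFP 1. One factor of weaker enrichment in shGFP 2 may account for part of it. The excess of summit reads over the genome background was lower in shGFP 2 in 240 of 250 shared regions, with a median ratio of 0.658, but scaling the shGFP 1 peaks by that ratio left 655 calls where shGFP 2 had 260. This stays open because the ratio can be measured only where shGFP 2 was called, which favours sites where it was high.

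The third pattern is a hypothesis that sites occupied in all 4 libraries lie near each other. Of 36 pairs of control regions within 100 kb of each other, 4 had both members in all 4 lists, against a mean of 0.303 after permuting which regions those were (permutation p = 0.0032). Without the chromosome 20 cluster, 1 of 21 pairs remained against a mean of 0.131 (permutation p = 0.1225), still 7.61-fold, so too few pairs are left to tell whether the pattern goes beyond that locus. A wide signal split into several calls is a possible explanation that stays open. Merging regions up to 10 kb apart left 1 of 9 pairs against a mean of 0.0654 (permutation p = 0.0643). The excess was 13.2-fold before and 15.3-fold after, but after merging it rests on 1 pair, so it cannot tell whether the pattern outlasts merging.

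In the 59 regions called in at least 1 library of each group, the local background of the input was higher in the shGFP comparison in 55, by a median of 1.58-fold. Of the 68 knockdown calls in control regions, 44 kept the smallest significance of their own list when set against the shGFP input. Regions without a call could not gain one in this comparison. Peaks with a neighbour within 100 kb made up 34.2% of shGFP 1, 17.3% of shGFP 2, 19.4% of shGDF6 1 and 13.3% of shGDF6 2.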
